A study of Mus musculus with 6 samples.

How the data were processed

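RNA was measured in 6 subcutaneous tumours of C57BL/6J mice, 3 from mice on a normal diet (ND) and 3 from mice on a high cholesterol diet (HCD). The diet and the number of each tumour were taken from the labels, which number the tumours 1 to 3 within a diet and do not state how the animals or tumours were separated as replicates, so the p-values measure only the spread between these samples. Per the labels' protocols, total RNA was isolated with a column kit and made into paired-end libraries with the TruSeq RNA kit.

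The authors deposited raw read counts per gene and FPKM values (a count scaled by gene length and library total) side by side for the same 34745 genes. Per the submitters' processing notes, the mm10 genome build, CASAVA 1.8, TopHat2 2.0.9, HTSeq and edgeR were used, with no role or order given for any of them. The annotation release, the strand setting and the treatment of reads with several matches were not given in the sources used here. The deposited counts were whole numbers, and the deposited FPKM values equalled a gene's count divided by the library total and a fixed gene length. Each of the 6 samples had its own column of each kind, and no other column of sample values was present. A count depends on how reads from overlapping genes and near-identical copies were shared out, so genes that share exons with a neighbour and genes with close copies were treated as uncertain.

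Library totals ran from 20351637 to 26228074 counts. A count of 0 in 1 library allowed a level of up to 0.114 to 0.147 CPM (3 counts of the library total), and over all 6 libraries up to 0.0228 CPM. These floors cover counting error only. Scaled counts (CPM) were computed here from the counts with library totals scaled by TMM factors, which ran from 0.979 to 1.02.

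The count test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with the diet as the only term and all 6 libraries in the fit. It was run in its legacy form, without adjusted deviances. Genes were kept by the default filter of the package (minimum count 10, minimum total 15), which left 15539 genes. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are log2 of HCD over ND with a prior count of 0.125. Standard errors were derived from the fold change and the F statistic, intervals are 95% intervals, and neither is given where a diet had no count.

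Before the data were examined, 30 gene lists were fixed, covering sterol and lipid metabolism, stress, cell cycle, interferon, antigen presentation, cell types that a tumour under the skin could hold, and checks of the samples. Each list with at least 3 tested members was compared with all other tested genes by camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, two-sided, with adjustment over the lists. The same lists were also tested with an estimated correlation and with fry, in the main fit of all 6 libraries only. List calls of every other fit and split used camera with the preset correlation. A list score is the mean over its tested genes of the log2 CPM of a library minus the mean of the gene over the 6 libraries. A further 7 lists (hepatocyte identity, hepatic transcription factors, mature liver, pigment cell core, immunoglobulin constant regions, lysosome, iron) were written after a first look at the data.

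The genes named in the text were set by a rule fixed before the data were examined. The rule took the 8 genes with the largest change in each direction among genes past the threshold with a mean of at least 1 CPM in the higher diet and with all 3 libraries of a diet above the other 3, or, where fewer than 3 genes passed, the 5 genes with the smallest p in that direction and the same minimum mean, passing over predicted genes without a name. It added, for each list, up to 2 members past the threshold over all genes or over the list alone, or else the member with the highest mean level, and finally a few genes fixed by name, of which Abca1 and Tyr are given. Some genes that the rule takes are not reported here, though they stayed in the tests and in the lists. Other list members, and the genes of the 7 later lists, were named after their values were seen.

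Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors and upper quartile factors in place of TMM, no filter and a stricter filter of 1 CPM in all 3 libraries of a diet, the DESeq2 Wald test, limma-voom, limma on log2(FPKM + 1) for genes above 1 FPKM in at least 3 libraries, pseudocounts of 0.1 and 5, no FPKM filter, the replicate number as a block, each library left out in turn, thresholds of 0.01 and 0.1, and a minimum change of 2-fold. After the data were seen, 4 alternatives were added: quasi-likelihood with adjusted deviances, robust empirical Bayes, a fit without HCD 1 and ND 2, and a fit with an immune score of each library as a covariate. The immune score is the mean of the list scores of T cells, NK and cytotoxic lymphocytes, B and plasma cells, macrophages and monocytes, and dendritic cells and MHC class II.

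Coordinates are those of the GENCODE M21 mouse annotation on GRCm38 (mm10), which held 34267 of the 34745 gene identifiers. The count test and camera were tested on 5 simulated sets drawn from the means, dispersions and library sizes of these libraries, with 200 changed genes in each and a mean of 15295 genes tested. The test recovered 17.2% of genes changed 1.5-fold, 50.8% of those changed 2-fold, 72.8% of those changed 3-fold and 87.2% of those changed 4-fold. False calls were 39 of 617. A list shifted by 0.50 on the log2 scale was called in 5 of 5 sets, and 1 unshifted list was called in all sets together. The simulated genes varied independently of each other.

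The 3 libraries of a diet were compared with each other before averaging. Chi-square per degree of freedom ran from 16.9 to 32.0 for pairs of the same diet, far above sampling noise, so no library was counted as a duplicate.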

Results

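RNA was sequenced from 6 tumours grown under the skin of C57BL/6J mice, 3 from animals on a normal diet (ND) and 3 from animals on a high cholesterol diet (HCD). The labels name the injected cells as B16F10, a line from a mouse melanoma. The libraries held 22864684 (ND 1), 26228074 (ND 2), 20622727 (ND 3), 20351637 (HCD 1), 20425576 (HCD 2) and 20918324 (HCD 3) counts, and 15539 genes had enough counts to be tested. The comparison asked which transcripts of the tumour tissue differed between the diets.

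The label of the tumours was first set against pigment cell genes. Tyr, which encodes the rate-limiting enzyme of melanin synthesis (ENSMUSG00000004651, chromosome 7, 87424771 to 87493512), had 0 counts in all 6 libraries, as did Dct, Mlana and Oca2. Over the 131411022 counts of the 6 libraries, a count of 0 allows a level of up to 0.0228 CPM. Tyrp1 had 1 count in total, Pmel averaged 0.672 ± 0.188 CPM (SD, n = 6) and Sox10 had counts in 2 of the 6 libraries. Part of the genes of hepatocytes were abundant in every library. Alb, which encodes serum albumin, averaged 3614 ± 530.2 CPM (SD, n = 6) and ranked 4 among all genes, with a lowest library of 2977 CPM. The alpha-fetoprotein gene Afp averaged 634 ± 151 CPM, the hepatocyte transcription factor gene Hnf4a 169 ± 35.1 CPM, the keratin genes Krt8 and Krt18 1044 ± 131 and 1725 ± 213 CPM, and Igfbp1 2237 ± 349.5 CPM (SD, n = 6 each). The tumours are called tumours labelled as B16F10 here. Other hepatocyte genes were near 0, among them Apoh at 0.129 CPM, Serpina1a at 0.128 CPM, Fgg at 0.216 CPM, Apoa2 at 0.459 CPM, Ahsg at 0.536 CPM and Vtn at 0.628 CPM. The pigment cell genes Pax3 and Slc24a5, at 1.88 and 1.77 CPM, had counts in all 6 libraries. The hepatocyte genes were chosen after their values were seen.

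**Figure D1:**
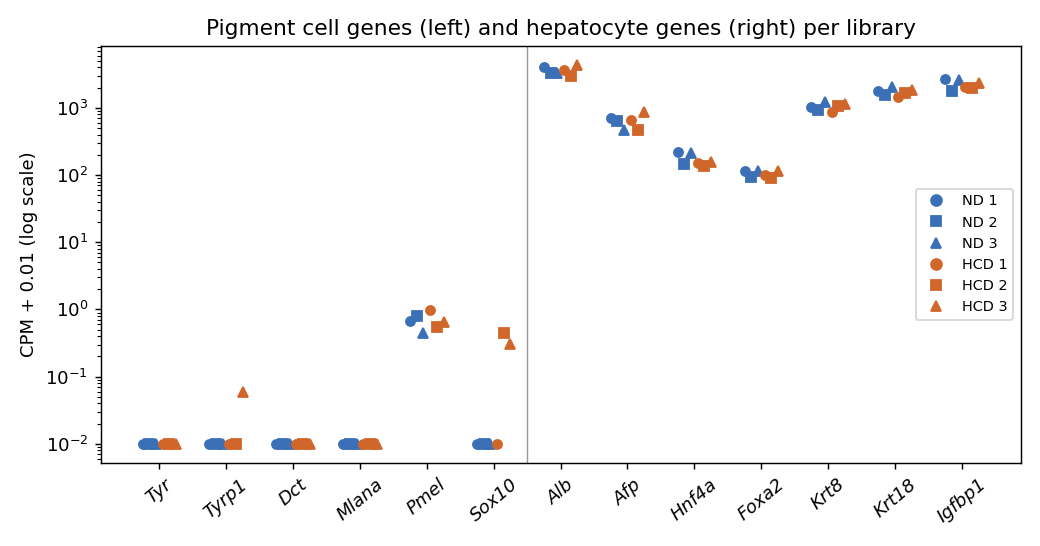
Level of pigment cell genes (left of the line) and hepatocyte genes (right) in each library, as CPM plus 0.01 on a log axis, so that points at the bottom are libraries with 0 counts. Colours mark the diet, and shapes mark the number of the tumour. Tyr, Dct and Mlana have 0 counts in all 6 libraries, while Alb lies between 2977 and 4370 CPM.

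Between the diets, T cell genes lay higher in HCD tumours, with positive fold changes for 21 of 21 tested members and a median log2 fold change of 0.75. Genes of cholesterol synthesis lay lower, with negative fold changes for 24 of 25 members and a median of -0.20, and neutrophil genes had a median of -0.53. No single gene passed the test in either direction. No list separated the diets fully: for 0 of the 30 lists did all 3 HCD libraries lie above, or all 3 below, the 3 ND libraries. By camera with the preset correlation 17 of 30 lists passed, 14 higher and 3 lower in HCD tumours, and with an estimated correlation 0 lists passed, the smallest adjusted p being 0.665. Over the 17 lists the estimated correlation ran from 0.29 for neutrophils to 0.93 for skeletal muscle, far above the preset value. The preset p-values therefore treat genes that vary together as nearly independent and overstate the evidence for a list.

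Among single genes, edgeR called 0 higher and 0 lower, with a smallest adjusted p of 0.839. The smallest adjusted p depended on the form of the test: with adjusted deviances edgeR gave 0.0939, also above the threshold of 0.05. At an unadjusted p under 0.05 there were 823 genes, 282 higher and 541 lower, where 777 are expected by chance. Leaving out 1 library moved the total by over 1.5 times in 3 fits: 154 higher and 224 lower without ND 1, 553 and 800 without ND 2, and 201 and 324 without ND 3. Without HCD 2 the directions were nearly even, 409 higher and 434 lower, and without HCD 3 there were 450 higher and 546 lower. The DESeq2 Wald test called 1 gene higher and 7 lower, while limma-voom and limma on log2(FPKM + 1) called 0. Without ND 2, edgeR called 2 genes lower, A2m (log2 fold change -1.75 ± 0.11 SE, adjusted p = 0.0399) and the neutrophil gene S100a9 (-1.66 ± 0.11 SE, adjusted p = 0.0399). In all 6 libraries A2m had a log2 fold change of -1.31 ± 0.53 SE and S100a9 of -1.28 ± 0.41 SE, with an adjusted p of 0.839 for both. All 3 HCD libraries lay above all 3 ND libraries for 4.75% of tested genes and below them for 6.36%, where chance gives 10% for both directions together.

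The gene with the smallest p was C5ar2, which encodes a receptor for the complement fragment C5a (ENSMUSG00000074361, chromosome 7, 16234585 to 16244154). Its level was 1.82 ± 0.268 CPM in ND and 0.129 ± 0.0735 CPM in HCD tumours (SD, n = 3 each), a log2 fold change of -3.76 ± 0.46 SE, with an edgeR adjusted p of 0.839 and a DESeq2 adjusted p of 0.00109. Its median count over the 6 libraries was 22.5, which describes neither diet, and its exons overlap the predicted gene Gm26473. In HCD 1 to HCD 3 its level was 0.193, 0.145 and 0.0488 CPM, where 3 counts are 0.143 to 0.147 CPM. The size of the fold change therefore rests on counts near the floor in HCD tumours. Dcun1d4, a gene of the cullin neddylation machinery (ENSMUSG00000051674, chromosome 5, 73481000 to 73560794), had 53.7 ± 1.25 CPM in ND and 37.1 ± 2.00 CPM in HCD tumours, a log2 fold change of -0.53 ± 0.07 SE, with a DESeq2 adjusted p of 0.00104. Mnt, which encodes a repressor that binds Max (ENSMUSG00000000282, chromosome 11, 74830920 to 74845725), had a log2 fold change of -0.68 ± 0.11 SE, with a DESeq2 adjusted p of 0.00471. Myo10, an unconventional myosin of filopodia (ENSMUSG00000022272, chromosome 15, 25622525 to 25813673), had 333 ± 25.3 against 250 ± 6.77 CPM, a log2 fold change of -0.41 ± 0.07 SE and a DESeq2 adjusted p of 0.00471. The fifth, Lmbr1l, had a log2 fold change of -0.49 ± 0.10 SE and passed neither test. DESeq2 also called Slc39a10, Slc38a2 and Gm11884 lower, with log2 fold changes of -1.08, -0.30 and -0.67 and adjusted p of 0.0117 for the first and 0.0153 for both others. The edgeR adjusted p of each of these genes was 0.839.

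In the other direction, among genes with a mean of at least 1 CPM in HCD tumours and with predicted genes passed over, the smallest p were those of Gpcpd1, Glul, Bpgm, Ighv1-63 and Them6. Gpcpd1 (ENSMUSG00000027346, chromosome 2, 132529082 to 132587729) had 61.2 ± 5.16 CPM in ND and 83.2 ± 6.00 CPM in HCD tumours, a log2 fold change of 0.44 ± 0.09 SE. The glutamine synthetase gene Glul (ENSMUSG00000026473, chromosome 1, 153899944 to 153909723) had 202 ± 22.1 against 295 ± 42.4 CPM, a log2 fold change of 0.55 ± 0.12 SE, and shares exon sequence with Teddm2. Them6 had a log2 fold change of 0.47 ± 0.12 SE and overlaps Slurp1. The immunoglobulin heavy chain segment Ighv1-63 had 0 counts in the 3 ND libraries and 2.00 ± 1.98 CPM in HCD tumours (SD, n = 3) and has close copies in the genome, between which the sharing of reads is unknown. DESeq2 called it, with an adjusted p of 0.00109, and edgeR gave an adjusted p of 0.839. The edgeR adjusted p of the other 4 genes was also 0.839.

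**Figure D2:**
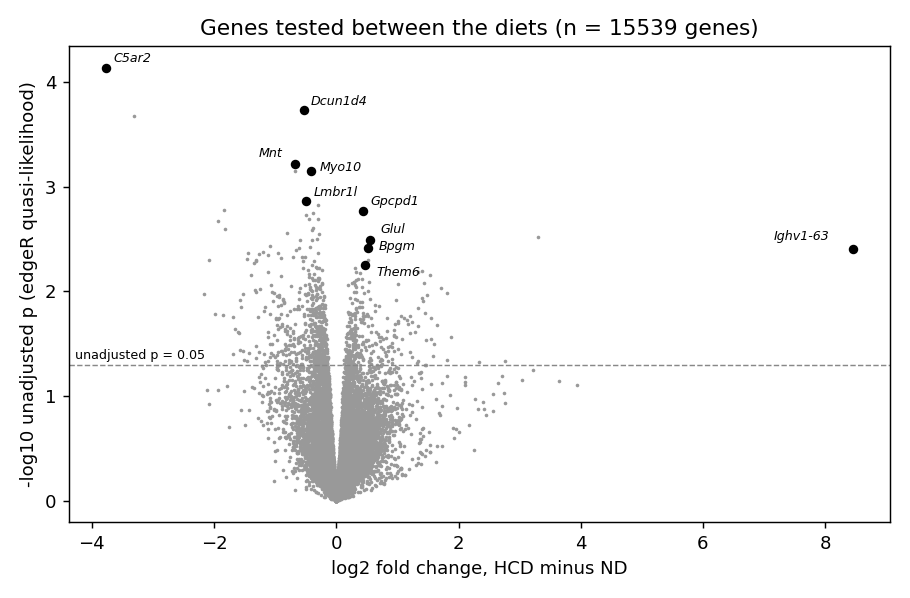
Each point is 1 of the 15539 tested genes, with the log2 fold change of HCD over ND on the horizontal axis and -log10 of the unadjusted p of edgeR on the vertical axis. The 5 named genes of each direction are in black, and none passed the adjusted threshold (smallest adjusted p 0.839). The position of Ighv1-63, which had 0 counts in ND, depends on the prior count of the fit.

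The cholesterol synthesis list passed camera with an adjusted p of 1.34e-05, and its adjusted p was 0.665 with an estimated correlation. The estimated correlation was 0.67, far above the preset value, so the smaller p counts genes that vary together as nearly independent. None of the list's 25 members passed over all genes, and 0 passed when adjusted over the list alone. Srebf2, which encodes a transcription factor that drives the pathway, had 287 ± 25.7 CPM in ND and 239 ± 35.5 CPM in HCD tumours, a log2 fold change of -0.27 ± 0.12 SE. Fdft1, the squalene synthase gene, had 48.0 ± 9.71 against 35.8 ± 6.69 CPM and Tm7sf2, a sterol reductase gene, 10.2 ± 1.99 against 7.40 ± 0.406 CPM. The list score averaged 0.10 ± 0.21 in ND and -0.10 ± 0.24 in HCD libraries (SD, n = 3 each). The lowest score was that of HCD 2, at -0.37, and ND 2, at -0.14, lay below HCD 1 and HCD 3. Without HCD 2 the median was -0.05 and the list no longer passed (adjusted p = 0.17), and without ND 1 it was -0.11.

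**Figure D3:**
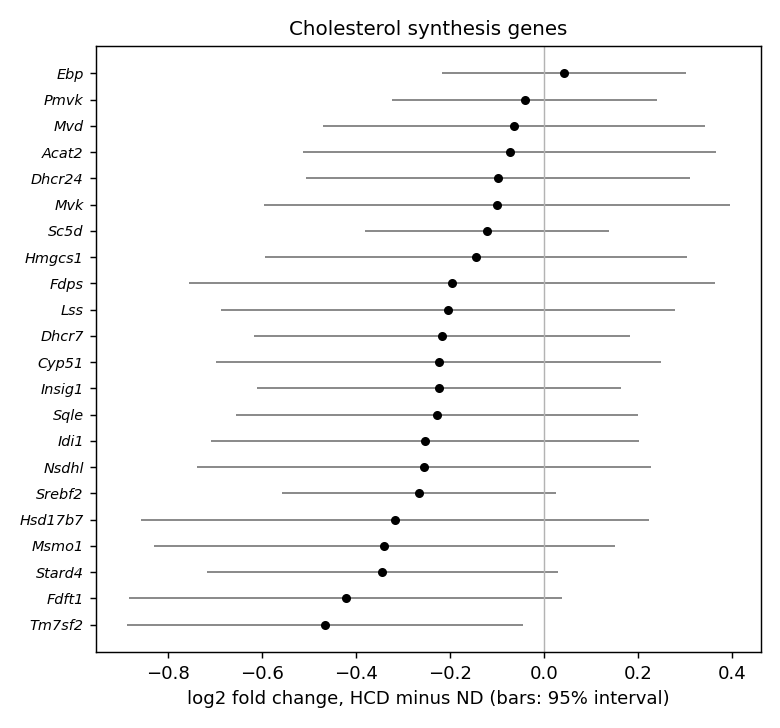
Log2 fold change of HCD over ND for genes of the cholesterol synthesis list reported here, with bars for the 95% interval. Among the genes shown Ebp alone lies above 0, and the interval lies entirely below 0 for Tm7sf2, which did not pass the adjusted threshold.

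Sterol efflux and lipid handling did not pass. The list driven by the sterol receptor LXR had a median of 0.05 (camera adjusted p = 0.308), with Abca1, a cholesterol exporter gene, at 164 ± 17.2 CPM in ND and 221 ± 66.3 CPM in HCD tumours. The log2 fold change of Abca1 was 0.43, with a 95% interval of -0.06 to 0.92 and an adjusted p of 0.839, and was 0.18 without HCD 2. Apoe, the list member with the highest level, had 3887 ± 394.6 against 3321 ± 832.6 CPM. Lipid uptake, storage and lysosomal handling had a median of 0.09 (adjusted p = 0.287), with Lrp1 at 605 ± 39.0 against 583 ± 67.3 CPM. Fatty acid oxidation had a median of 0.06 (adjusted p = 0.168). The unfolded protein response had a median of -0.04 (adjusted p = 0.368), with Hspa5 at 985 ± 91.2 against 891 ± 24.4 CPM. Without HCD 1 the lipid uptake list passed, with a median of 0.05 and an adjusted p of 0.0151, and without HCD 2 its median was 0.01 (adjusted p = 0.978). Over the 6 fits without 1 library the median ran from 0.01 (without HCD 3) to 0.08 (without ND 1) for the LXR list. It ran from 0.03 (without HCD 1) to 0.10 (without ND 1) for fatty acid oxidation and from -0.09 (without HCD 2) to -0.00338 (without HCD 1) for the unfolded protein response, and none of these 3 lists passed in any of the fits.

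The lists of lymphocytes and antigen presentation lay higher in HCD tumours. T cell genes passed camera with an adjusted p of 2.76e-09, against an adjusted p of 0.665 with an estimated correlation. Their members included Cd3e, a part of the T cell receptor complex, at 4.42 ± 2.62 CPM in ND and 8.57 ± 3.68 CPM in HCD tumours, and Thy1 at 44.5 ± 7.48 against 48.2 ± 14.9 CPM (log2 fold change 0.11, and -0.14 without HCD 2). NK and cytotoxic lymphocyte genes had a median of 0.64 with 17 of 17 members positive (adjusted p = 2.42e-06, and adjusted p = 0.665 with an estimated correlation), with the granzyme gene Gzmb at 9.92 ± 4.64 against 16.8 ± 9.08 CPM. MHC class I antigen presentation had a median of 0.28 with 14 of 14 members positive (adjusted p = 5.03e-06, and adjusted p = 0.665 with an estimated correlation), with B2m at 2201 ± 294.1 against 2429 ± 266.2 CPM. Dendritic cell and MHC class II genes had a median of 0.50 with 17 of 18 positive (adjusted p = 1.30e-05, and adjusted p = 0.665 with an estimated correlation), with the invariant chain gene Cd74 at 1012 ± 427.2 against 1481 ± 386.5 CPM. No member of these 4 lists passed over all genes or adjusted over the list alone. The estimated correlation was 0.90 for T cells, 0.64 for NK, 0.83 for MHC class I and 0.77 for dendritic cell and MHC class II genes. All 4 values lay far above the preset one, so the preset p-values overstate the evidence. For the same reason the 21 positive T cell genes are not 21 separate observations.

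ND 1 had the lowest T cell score of the 6 libraries, -1.60, and HCD 2 the highest, 1.01. Between them lay HCD 3 at -0.17, ND 2 at 0.04, ND 3 at 0.25 and HCD 1 at 0.47. Without ND 1 the T cell median was 0.34, and without HCD 2 it was 0.43. By camera the list was past the threshold in both fits (adjusted p = 0.000443 and 0.00113). All fits without a library used the preset correlation, so they do not test whether the calls hold with an estimated one. The MHC class I median was 0.09 without ND 1 and 0.16 without HCD 2, and the NK median 0.26 without HCD 2, all still past the threshold. The dendritic cell and MHC class II list had a median of 0.20 without ND 1 and 0.78 without ND 2, and did not pass without HCD 2 (median 0.30, adjusted p = 0.0607).

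**Figure D4:**
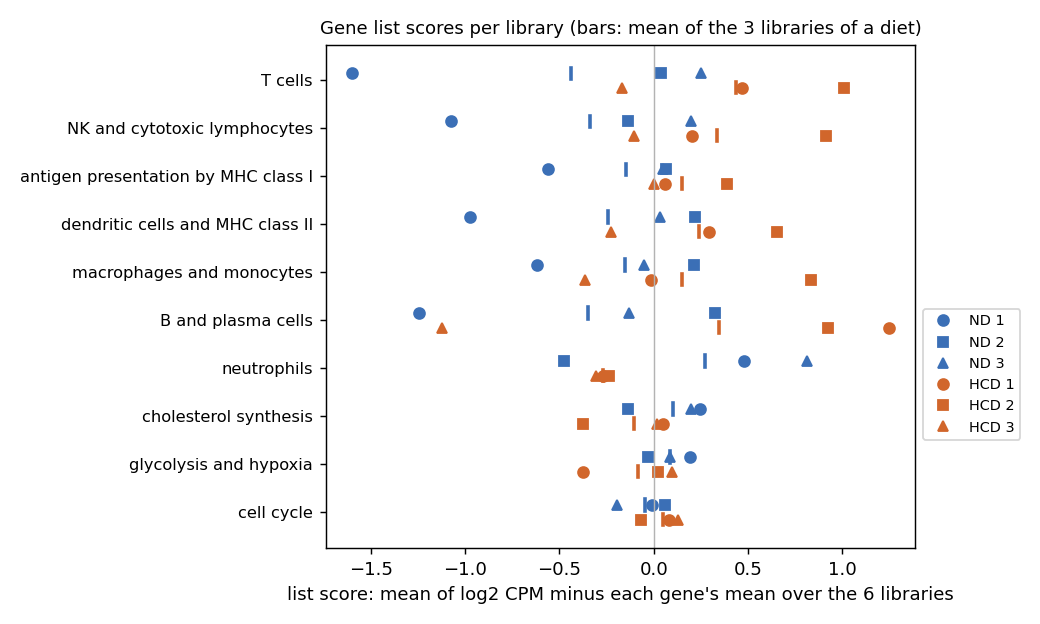
Score of 10 gene lists in each library, as the mean log2 CPM of the list's genes relative to their mean over the 6 libraries, with bars for the mean of the 3 libraries of a diet. The diets overlap in every list shown, and T cell scores run from -1.60 in ND 1 to 1.01 in HCD 2.

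Other leucocyte lists also passed with the preset correlation. Macrophage and monocyte genes had a median of 0.40 with 19 of 22 positive (adjusted p = 0.00185, and adjusted p = 0.665 with an estimated correlation), and Lyz2 had 207 ± 92.4 CPM in ND and 322 ± 169 CPM in HCD tumours. Without ND 1 the macrophage median was 0.16 and without HCD 2 0.01, and the list passed in neither fit, and without ND 2 it was 0.60. B and plasma cell genes had a median of 0.77 with 11 of 12 positive (adjusted p = 0.00241, and adjusted p = 0.665 with an estimated correlation). Igkc, the kappa light chain constant region, had 43.9 ± 31.4 against 75.4 ± 51.4 CPM. The B cell list did not pass without ND 1, HCD 1 or HCD 2 (medians 0.63, 0.50 and 0.46), and its median was 1.56 without ND 2 and 1.37 without HCD 3. Interferon response genes had a median of 0.21 with 21 of 28 positive (adjusted p = 0.0199, and adjusted p = 0.684 with an estimated correlation), with Gbp2 at 427 ± 175 against 600.4 ± 235 CPM. This median turned to -0.06 without ND 1 and -0.07 without HCD 2, and was 0.37 without ND 3 and 0.35 without HCD 1. T cell checkpoint genes had a median of 0.25 with 15 of 17 positive (adjusted p = 0.0192, and adjusted p = 0.665 with an estimated correlation), and of 0.05 without ND 1, -0.02 without HCD 2, 0.39 without ND 3 and 0.42 without HCD 3. The checkpoint ligand gene Cd274 had 125 ± 34.8 against 127 ± 42.7 CPM, a log2 fold change of 0.03 (-0.15 without ND 1 and -0.26 without HCD 2). Mast cell and eosinophil genes had a median of 0.64 (adjusted p = 0.0192, and adjusted p = 0.665 with an estimated correlation), and of 0.33 without ND 1 and 0.03 without HCD 2, where the call was lost, and 0.99 without ND 2. The mast cell tryptase gene Tpsb2 had 14.9 ± 9.11 against 27.1 ± 15.2 CPM.

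Neutrophil genes were the leucocyte list with a negative median, -0.53, with 8 of 13 members negative (adjusted p = 3.75e-05, and adjusted p = 0.665 with an estimated correlation). Csf3r, the receptor gene for the granulocyte growth factor (ENSMUSG00000028859, chromosome 4, 126024550 to 126044440), had 51.3 ± 7.75 CPM in ND and 35.4 ± 7.32 CPM in HCD tumours, a log2 fold change of -0.53 ± 0.17 SE. S100a9 had 34.4 ± 17.9 against 14.1 ± 1.06 CPM and Cxcr2 12.6 ± 5.03 against 6.75 ± 0.405 CPM, and the smallest p adjusted over the list alone was 0.0703. The neutrophil score was 0.48 in ND 1 and 0.81 in ND 3, and ND 2 had the lowest score of all libraries, -0.48. The median was -0.36 without ND 3 and -0.94 without HCD 2, with the list past the threshold in both fits at the preset correlation.

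Glycolysis and hypoxia genes had a median of -0.17 with 20 of 24 negative (adjusted p = 4.80e-05, and adjusted p = 0.665 with an estimated correlation). Gapdh had 3474 ± 190.6 CPM in ND and 3416 ± 528.3 CPM in HCD tumours (log2 fold change -0.02, and 0.02 without ND 1, 0.06 without HCD 1 and 0.02 without HCD 2), and the hypoxia gene Car9 12.0 ± 0.430 against 7.89 ± 1.66 CPM. Without HCD 1, the library with the lowest score of -0.37, the median was -0.05 and the list did not pass (adjusted p = 0.341), and it was -0.07 without ND 1 and -0.29 without HCD 3. Cell cycle genes had a median of 0.08 with 21 of 26 positive (adjusted p = 0.00362, and adjusted p = 0.677 with an estimated correlation), with Mki67 at 733 ± 93.0 against 771 ± 34.2 CPM (log2 fold change 0.07, and -0.03 without ND 3). The cell cycle median was 0.01 without ND 3 and 0.06 without HCD 3, where the call was lost, and 0.15 without ND 2 and 0.14 without HCD 2.

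Skeletal muscle and adipocyte scores differed more between libraries of a diet than between the diets. Skeletal muscle scores were 3.29 in ND 2 and 3.80 in HCD 1 against -3.04 in ND 1 and -2.82 in HCD 3, and the myosin gene Myh4 had 234 ± 405 CPM in ND and 147 ± 228 CPM in HCD tumours (log2 fold change -0.67 ± 2.43 SE, and 9.01 without ND 2). The muscle list had a median of 0.24 (adjusted p = 0.0382, and adjusted p = 0.684 with an estimated correlation), which ran from -2.22 without HCD 1 to 4.84 without ND 2. It turned negative without ND 1 (-0.21) and ND 3 (-0.19) as well, and was 0.70 without HCD 2 and 0.82 without HCD 3. Adipocyte genes had a median of 0.94 with 9 of 9 positive (adjusted p = 0.0382, and adjusted p = 0.665 with an estimated correlation). The adipocyte list passed only without ND 2 (median 2.41) and without HCD 3 (0.51) among the fits that left out 1 library, and its median was 0.15 without ND 1, 0.18 without ND 3, 0.16 without HCD 1 and 0.34 without HCD 2. Pnpla2 had 64.8 ± 4.62 against 66.6 ± 5.07 CPM (log2 fold change 0.04, and -0.01 without ND 2 or HCD 2). Endothelial and pericyte genes had a median of 0.28 with 16 of 19 positive (adjusted p = 0.00356, and adjusted p = 0.665 with an estimated correlation). Their median was 0.04 without HCD 2, where the call was lost, and 0.45 without HCD 3. The pericyte gene Rgs5 had 161 ± 32.8 against 179 ± 53.0 CPM (log2 fold change 0.16, and -0.11 without HCD 2). Erythroid genes had a median of 0.52 with 6 of 7 positive (adjusted p = 0.0137, and adjusted p = 0.665 with an estimated correlation), and of 0.15 without ND 1 and 0.05 without HCD 3, where the call was lost. In this list Bpgm, which encodes bisphosphoglycerate mutase (ENSMUSG00000038871, chromosome 6, 34476207 to 34505613), had 16.2 ± 1.01 against 23.3 ± 3.03 CPM. It was the 1 list member that passed when adjusted over the list alone, by edgeR with an adjusted p of 0.0269, against 0.839 over all genes. That adjustment was made within each of the 30 lists without a correction over the lists, so 1 such member is weak evidence.

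The remaining lists did not pass. Fibroblast and matrix genes had a median of 0.01 (adjusted p = 0.898), with Dcn at 1745 ± 178 against 1608 ± 231 CPM. That list was lower without HCD 2 (median -0.33, adjusted p = 0.000495) and higher without HCD 3 (0.22, adjusted p = 0.000317), with a mean of 0.07 and a downward camera direction in all 6 libraries and a median of -0.13 without ND 2. Genes of epithelial-mesenchymal transition and invasion had a median of -0.01 (adjusted p = 0.0802), with fibronectin, Fn1, at 7826 ± 1169 against 6259 ± 434.8 CPM, and passed without ND 2 (-0.11, adjusted p = 0.00382) and without HCD 2 (-0.16, adjusted p = 0.00486), with a median of 0.06 without HCD 1. Inflammatory cytokines had a median of 0.10, a mean of -0.03 and a downward camera direction (adjusted p = 0.635), and their median was -0.39 without HCD 2 (adjusted p = 0.00113) and -0.05 without ND 1. Their member with the highest level was Tgfb1, at 134 ± 15.3 against 122 ± 12.1 CPM. The melanocytic list had 12 of 22 members tested, with a median of 0.12, a mean of -0.10 and a downward direction (adjusted p = 0.595), and its median was -0.04 without HCD 2. Its member with the highest level was Met, at 250 ± 21.3 against 228 ± 16.7 CPM. Keratinocyte genes had a median of 0.12 (adjusted p = 0.308), which passed without HCD 1 (0.33, adjusted p = 0.0416) and was -0.03 without HCD 3, with Dsp at 276 ± 28.5 against 253 ± 36.6 CPM. Schwann cell genes had a median of 0.29 (adjusted p = 0.110), which passed without HCD 3 (0.42, adjusted p = 0.00144) and was 0.07 without HCD 2 and 0.14 without HCD 1, with Pmp22 at 27.1 ± 4.45 against 29.4 ± 3.91 CPM. Sex-linked genes had a median of 0.25 (adjusted p = 0.627), and of -0.15 without HCD 2, with Xist, which overlaps Tsix, at 2427 ± 323.8 against 2107 ± 102.7 CPM. Mitochondrially encoded RNA had a median of -0.05 (adjusted p = 0.260), with mt-Co1 at 14991 ± 806 against 14698 ± 1222 CPM (log2 fold change -0.03, and 0.02 without ND 1 or HCD 2). Early response genes had a median of 0.06 (adjusted p = 0.868), which was 0.0041 without HCD 3, 0.01 without ND 2, 0.02 without HCD 2 and 0.10 without ND 1, with Hsph1 at 221 ± 32.0 against 230 ± 63.5 CPM (log2 fold change 0.06, and -0.05 without ND 1 and -0.12 without HCD 2). The mitochondrial list passed without ND 3 (-0.09, adjusted p = 0.0170) and without HCD 1 (-0.09, adjusted p = 0.0439), and its median was 0.0006 without ND 1 and 0.02 without HCD 2.

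The first principal component of the 6 libraries carried 49.9% of the variance and put HCD 1, HCD 2 and ND 2 on the positive side and ND 1, ND 3 and HCD 3 on the other, across the diets. The skeletal muscle and adipocyte scores divided the libraries in the same way by their sign. None of the 17 list calls held with an estimated correlation, and none held with fry, where the smallest adjusted p was 0.752. Across the fits that left out 1 library, 4 of the 17 calls were kept in every fit: T cells, NK and cytotoxic lymphocytes, MHC class I and neutrophils. Those fits used the preset correlation only.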

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

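The fits with adjusted deviances, with robust empirical Bayes, without the muscle-rich libraries HCD 1 and ND 2, and with the immune score as a covariate were chosen after the data were seen, and the others before. Over all alternatives, 756 of 793 gene values and 508 of 660 list values kept their direction and their side of the threshold. No gene passed in the main fit, so a gene value was kept whenever its sign held and it stayed uncalled. The alternatives reuse the same libraries, so these shares are no independent support. Of the list values, 98 kept the direction and lost the call, 19 gained a call and 35 reversed, and of the gene values 32 reversed and 5 gained a call. A count of 0 excludes only levels above 0.114 to 0.147 CPM in a library, and genes changed 1.5-fold were recovered in 17.2% of simulated cases. The cause was not tested for any change below.

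DESeq2 called 1 gene higher and 7 lower, where edgeR called 0 and 0. The number of lists past the threshold was 17, and 11 with limma on log2(FPKM + 1) and no filter, 5 with the immune score as a covariate, 0 with an estimated correlation and 0 with fry. With the immune score as a covariate 1 gene was lower, Igha (log2 fold change -2.85, adjusted p = 0.000864). Leaving out each library in turn gave 9 (without ND 1) to 18 (without ND 2) lists, 0 to 0 genes higher and 0 to 2 genes lower (2 without ND 2).

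With the replicate block 0 genes passed in either direction (smallest adjusted p 0.865), and 14 lists were higher and 3 lower. The skeletal muscle call was lost (adjusted p = 0.0913) and lipid uptake gained a call (adjusted p = 0.0278). The medians or fold changes that reversed were fibroblasts -0.0443 and Myh4 0.50. Deviations from the diet mean correlated at -0.307, 0.140 and 0.0832 between libraries of the same number, so the numbers were not read as pairs.

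Other reversed values were inflammatory cytokines -0.0228, fibroblasts -0.0818 and Myh4 2.18 with limma-voom; fibroblasts -0.0125 and Myh4 0.58 with limma on log2(FPKM + 1), with and without a filter; fibroblasts -0.0601 and Myh4 1.52 with log2(FPKM + 0.1). Myh4 was 0.0812 with log2(FPKM + 5). Without HCD 1 and ND 2, fibroblasts were -0.0957, Gapdh 0.0400 and Myh4 5.75. With the immune score as a covariate, lists reversed to interferon -0.0978, checkpoint -0.0667, inflammatory cytokines -0.0762, B and plasma cells -0.0797, macrophages -0.0615, melanocytic genes -0.0919, fibroblasts -0.157, adipocytes -0.0837, skeletal muscle -1.61, Schwann cells -0.0230, sex-linked genes -0.139 and mitochondrial RNA 0.0461. Genes reversed in that fit were Gapdh 0.0862, Cd274 -0.237, Thy1 -0.125, Igkc -0.471, Lyz2 -0.0938, Rgs5 -0.0959, Pmp22 -0.000804, mt-Co1 0.0570 and Hsph1 -0.245.

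The ranges over the 6 fits without 1 library, for results that reversed in at least 1 of them, were: invasion genes -0.16 to 0.0597, fibroblasts -0.33 to 0.22, inflammatory cytokines -0.39 to 0.22, interferon -0.0682 to 0.37, keratinocytes -0.0270 to 0.36, melanocytic genes -0.0402 to 0.16, mitochondrial RNA -0.0934 to 0.0242, sex-linked genes -0.15 to 0.43, skeletal muscle -2.22 to 4.84 and checkpoint genes -0.0170 to 0.42. For genes they were Cd274 -0.26 to 0.25, Gapdh -0.16 to 0.0590, Hsph1 -0.12 to 0.26, Mki67 -0.0273 to 0.15, mt-Co1 -0.10 to 0.0242, Myh4 -3.92 to 9.01, Pnpla2 -0.0136 to 0.0932, Rgs5 -0.11 to 0.34 and Thy1 -0.14 to 0.30.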

Other observations

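The gene lists of this part and the patterns weighed in it were chosen after a first look at the data. Needed outcomes were written before the test for explanations of the pigment and hepatocyte, T cell and cholesterol patterns, and for the splits. None was written for the camera tests of the 7 later lists, for Igha over its list, or for the correlations of Y-linked genes and Xist. Lysosomal genes lay higher in HCD tumours, with a median log2 fold change of 0.18 and 17 of 20 members positive (camera adjusted p = 8.44e-05 over the 7 later lists, and adjusted p = 0.798 with an estimated correlation). The cathepsin gene Ctsz had 296 ± 40.5 CPM in ND and 372 ± 15.0 CPM in HCD tumours, and the saposin precursor gene Psap 934 ± 290 against 1328 ± 321.4 CPM (SD, n = 3 each). No member of the list passed when adjusted over the list alone. Macrophage genes moved with the list: the lowest score was that of ND 1 (lysosome -0.35, macrophages -0.62) and the highest that of HCD 2 (0.34 and 0.83), though HCD 3 had 0.02 and -0.36. Iron storage and handling genes had a median of 0.30 (adjusted p = 0.532), with the ferritin gene Fth1 at 1243 ± 157 against 1688 ± 279 CPM and the transferrin receptor gene Tfrc at 182 ± 68.8 against 103 ± 20.3 CPM.

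Immunoglobulin constant region genes had a median of 0.84 (adjusted p = 0.532), with members on both sides of 0. Igha, the heavy chain of IgA, had 44.2, 128 and 105 CPM in ND 1 to ND 3 and 22.1, 33.3 and 10.3 CPM in HCD 1 to HCD 3, a log2 fold change of -2.08 ± 0.51 SE. It was lower by edgeR when adjusted over the list alone (adjusted p = 0.0496), against an adjusted p of 0.839 over all genes. Since the list was written after a first look at the data, passing over it is no independent support. Ighg1, the heavy chain of IgG1, had 26.8 ± 39.7 against 160 ± 130 CPM. Between the diets, hepatocyte identity genes had a median of -0.05 (adjusted p = 0.532), hepatic transcription factors of -0.02 (adjusted p = 0.744), mature liver genes of 0.18 (adjusted p = 0.594) and pigment cell genes of 0.08 (adjusted p = 0.744).

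In all 6 libraries, most of the 11 pigment cell genes were near 0 and part of the 27 hepatocyte identity genes abundant, in tumours labelled as B16F10, while hepatocyte genes such as Apoh (0.129 CPM) were also near 0. Normal liver within a melanoma was argued against, since the median of 22 mature liver genes was 0.106 CPM, 0.00293% of the albumin level, although single genes such as Ass1, at 196 CPM, lay higher. B16F10 cells that had lost only their pigment genes were also argued against, since 10 hepatic transcription factors had a median of 19.3 CPM. A tumour of the hepatocyte lineage remains a candidate explanation, since 8 of these 10 factors exceeded 1 CPM in every library. When and how such cells or samples would have come under this label was not tested.

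T cell, NK and antigen presentation genes lay higher in HCD tumours by camera with the preset correlation, with an adjusted p = 0.665 with an estimated correlation for each of these lists. The muscle-rich libraries HCD 1 and ND 2 were argued against as the whole cause, since the T cell median was 0.90 without both, against 0.75 with all libraries. That fit cannot decide on muscle content in general. It kept ND 1 and HCD 2, which had the lowest and highest T cell scores and muscle scores of -3.04 and 0.78. The part of ND 1 stays open. Without it the T cell median was 0.34, low enough to meet the outcome written beforehand for ND 1 as the cause. But ND 1 was picked for its low T cell score, so a smaller median without it decides nothing. An effect of the diet remains open and untested beyond the comparison itself.

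Cholesterol synthesis genes lay lower in HCD tumours by camera with the preset correlation (adjusted p = 0.665 with an estimated correlation). A larger share of host cells that diluted tumour transcripts cannot be told apart from other causes, since the hepatocyte identity median was -0.0548, between the -0.20 of the cholesterol list and 0. Variation of the libraries along the immune score is a candidate explanation, since the cholesterol median was -0.0299 with that score as a covariate. The score itself averaged higher in HCD than in ND libraries, so the covariate also removes part of any diet difference.

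The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes higher and 0 lower by edgeR, and the highest of the other splits 0 and 0, so 10 and 10 of the 10 splits gave as many. With a count of 0 in the real split that outcome was fixed, so it decides nothing. At an unadjusted p under 0.05 the real split gave 823 genes and the highest other 1801, and DESeq2, limma-voom and limma on log2(FPKM + 1) called 8, 0 and 0 genes in the real split. For lists the real split gave 17 and the highest other 21, and 6 of the 10 splits gave as many as the real one. With the side of ND 1 as the reference, the T cell median of the real split, 0.75, ranked 3 of 10 from the highest. The highest was 1.08, with ND 1, ND 2 and HCD 3 as the reference. The cholesterol median of the real split, -0.20, ranked 4 of 10 from the lowest. The lowest was -0.38, with ND 1, ND 3 and HCD 1 as the reference. The split that set ND 1, ND 3 and HCD 3 against the rest gave the 1801 genes, which points to a structure of the samples across the diets. Skeletal muscle and adipocyte scores were both negative in ND 1, ND 3 and HCD 3 and both positive in the rest. Whether such tissue made the structure was not tested.

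The summed level of Y-linked genes was 30.6, 46.6 and 44.4 CPM in ND 1 to ND 3 and 45.9, 71.2 and 33.9 CPM in HCD 1 to HCD 3, and correlated with the immune score of the library (r = 0.939, adjusted p = 0.025 by exact permutation; r = 0.896 without ND 1 and HCD 2). Xist had r = -0.780 (adjusted p = 0.0806; r = 0.50 without ND 1 and HCD 2). The sex of the mice was not given in the sources used here. The mitochondrial look-alike genes Gm10925, Gm28437, Gm28661 and Gm29216 on chromosome 1 averaged 2445, 2391, 2212 and 1253 CPM.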
